A study of Mus musculus with 9 samples.

How the data were processed

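The series holds RNA sequencing of whole pancreas dissected from mouse embryos at embryonic day 15.5, with 9 libraries in 3 groups: wild type, Blinc1 heterozygotes and Blinc1 knockouts, 3 libraries each. Blinc1 is a long noncoding RNA gene beside Nkx2-2, the gene of an islet transcription factor. Per the labels, the embryos had a mixed C57BL/6 and 129Sv background, and libraries were made from total RNA with a TruSeq kit and read on a HiSeq2000. The labels do not say whether the libraries of a group came from separate embryos or litters, so the p-values measure only the spread between these samples. Groups and replicate numbers were taken from the sample titles.

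The deposited FPKM values (fragments scaled to transcript length and to the number of mapped fragments) came with lower and upper confidence bounds, also in FPKM, and a status word for each gene, per the file headers. Reads were mapped to mm9 with TopHat 2.0.4, allowing 4 mismatches and at most 10 hits per read, per the labels. CASAVA 1.8.2, Cufflinks and DESeq stand in the submitters' processing notes, and the column layout is that of a Cufflinks gene table, per the file headers. The gene annotation and whether counting used strand are not given in the sources used here. The result of the submitters' own DESeq comparison was not analysed here.

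Each deposited table listed the same 23699 loci under 23235 gene symbols, and the FPKM of the 248 symbols with more than 1 locus were summed. Estimates marked as failed for excess data were listed at 0 and were treated as missing, which removed 4 symbols, all genes of digestive enzymes of the exocrine pancreas (Amy2a2, Amy2a5, Ctrb1 and Pnliprp1). These failures for excess data were in heterozygote replicates 2 and 3 (2 and 1 loci) and knockout replicates 2 and 3 (5 and 1), and in no wild-type library. Other rows bore the status FAIL, from 4 in heterozygote replicate 1 to 14 in knockout replicate 1, and 10, 10 and 7 in the wild types. They kept their listed values, as did the 284 or 285 rows per library marked LOWDATA. Amy2a5, Ctrb1 and Pnliprp1 belong to the acinar list, which was tested without them. Positions are given 1-based on mm9. They were checked against the GENCODE annotation of the same assembly, where 21647 of 22987 single-locus symbols were found by name and 99.64% of those overlapped.

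Read counts were not used as such, because the deposited unit is FPKM. The upper bound lies 2 standard errors above each FPKM if the error is that of counting, which gives an implied number of fragments per gene. Of genes with fewer than 500 implied fragments, 73.83% to 74.74% per library came out whole within 0.05. The implied totals were 19532984 to 25437255 fragments per library. Library-wide rank correlations (Spearman) were between 0.9783 and 0.9915.

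Tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using an intensity trend in the empirical Bayes step, all 9 libraries in 1 fit and genotype as the only term. The design, the lists and the rule for named genes were fixed before the data were examined, with a count model for read counts and this limma test for FPKM, and the FPKM branch applied. A gene was tested if it reached 1 FPKM in at least 3 libraries, which left 13306 genes. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low levels. A permutation test of 3 libraries against 3 cannot give a p below 0.1.

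Of 22 fixed gene lists, the sex list served only to read the sex of each embryo, and the other 21 were tested with limma's camera at a preset inter-gene correlation of 0.01. They covered islet hormones, islet transcription factors, beta cells, alpha cells, the delta, epsilon and PP cells, endocrine progenitors, secretory granules, acinar cells, duct and trunk, mesenchyme, endothelium, neurons and glia, erythroid cells, immune cells, gut and stomach, liver, cell cycle, immediate early and heat shock genes, hypoxia, the unfolded protein response, and neighbours of Nkx2-2. Each was also tested with an estimated correlation and with fry. The genes named in the text follow a fixed rule: Nkx2-2 and a set of core pancreas genes for knockout against wild type; up to 4 members with the smallest p of each list that was called; where fewer than 5 genes passed, the 3 higher and the 3 lower with the smallest p; up to 3 of the highest-level genes of the sex, erythroid, immune, gut, liver and stress lists; and genes within 1 Mb of Nkx2-2 that passed over that list alone. How many members to name within these limits was set only after the alternatives had first been run on all of them: the 3 with the smallest p per called list in knockout against wild type, 2 in the other comparisons, and 1 gene of highest level per list from other tissues. Fewer are named where a paragraph covers many lists. Genes named outside the rule are said to be so. Some core genes under the rule are not reported here.

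The tests were run first on simulated values for the 13306 genes, with the layout of the knockout and wild-type comparison. Of 100 genes changed by a factor of 2, 76% were recovered, and of 100 changed by a factor of 4, 98% were recovered, all in the right direction. Another 15 unchanged genes were called. Of 10 lists of 20 genes shifted by 0.5 on the log2 scale, 10 were called, and of 30 unshifted lists, 0 were called. The simulated genes varied independently of each other, so this does not check the list test on lists with correlated members. In the data the estimated correlation reached 0.61, for endothelium.

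The alternatives fixed in advance were the replicate number as a block, each of the 9 replicates left out in turn, only the compared genotypes in the fit, sex as a covariate, no intensity trend, quantile normalization, no filter on low values, a filter of 5 FPKM, a pseudocount of 0.1, array weights, a rescaling that leaves out acinar and haemoglobin genes, other list tests, an adjusted p threshold of 0.1, and windows of 5 and 10 Mb around Nkx2-2. Chosen after the data were seen were a fit without heterozygote replicate 1 and knockout replicate 1, limma's voom on the implied fragments, and a fit without small RNA genes. Figures were drawn with matplotlib 3.10.9.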

Results

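Whole pancreas of e15.5 mouse embryos was profiled in 9 libraries: 3 wild type, 3 labelled heterozygous and 3 labelled knockout for the long noncoding RNA gene Blinc1. At this stage the pancreas holds acinar cells, duct and trunk epithelium, endocrine cells and their progenitors, together with mesenchyme, vessels, nerves and blood. The depth implied by the confidence bounds was 19532984 to 25437255 fragments per library. Group values are mean FPKM ± SD over 3 libraries. Xist, the RNA of the inactive X chromosome, was at 35 to 40.3 FPKM in wild-type replicate 3, heterozygote replicate 3 and all 3 knockout libraries. In the other 4 libraries it was at 0.0608 FPKM or less, and the Y-linked genes Ddx3y and Eif2s3y were at 14.82 to 16.17 and 28.61 to 34.25 FPKM, so all knockout libraries came from female embryos and only 1 library of each other group did.

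The targeted locus was examined first. Blinc1 itself was not analysed here under that name. Nkx2-2as, a long intergenic noncoding RNA on the plus strand (mm9 chromosome 2, 147009819 to 147157417) whose 5' part overlaps the minus-strand gene Nkx2-2, was at 0.142 FPKM or less in every library. AI646519, a processed transcript at 147187279 to 147188529, was listed at 0 in all 9 libraries. These levels are too low to check the genotype labels. Nkx2-2 (chromosome 2, 147003282 to 147012138, protein coding), which encodes a homeodomain factor required for islet cell development, was at 20.8 ± 5.18 in wild type (SD, n = 3), 12.9 ± 6.32 in heterozygotes and 12.2 ± 11.1 in knockouts. The libraries differed within groups. Nkx2-2 was at 15.2, 21.7 and 25.5 FPKM in the wild-type libraries and at 6.08 and 5.48 FPKM in the libraries labelled knockout replicates 2 and 3. In the library labelled knockout replicate 1 it was at 24.9 FPKM, from 1144 implied fragments. In the heterozygotes it was at 19 and 13.4 FPKM in replicates 2 and 3, but at 6.37 FPKM in the library labelled heterozygote replicate 1, from 238.2 implied fragments. The difference between knockout and wild type was -1.01 on the log2 scale (SE 0.53, limma adjusted p = 0.58). It was -1.66 without the library labelled knockout replicate 1 and -0.66 without knockout replicate 3. Nkx2-2 is not the targeted gene, so its level does not check the labels, and the directions given below are those of the groups as labelled.

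Expression of hormone genes in the libraries labelled knockout differed most at the insulin genes and at somatostatin, without passing the test. Ins1 (chromosome 19, 52338813 to 52339948) was at 609 ± 163 in wild type and 365 ± 227 in knockouts (log2 change -0.87, SE 0.40), and Ins2 (chromosome 7, 149864561 to 149865613) at 2660 ± 529 and 1700 ± 719 (-0.70, SE 0.30). Sst, the hormone of delta cells (chromosome 16, 23889667 to 23890930), was at 166 ± 21.7 and 343 ± 167 (0.89, SE 0.41). Gcg, the hormone gene of alpha cells, was at 913 ± 120 and 813 ± 96.6 (-0.17, SE 0.15), Ghrl at 159 ± 54.3 and 115 ± 52.9 (-0.50, SE 0.33), Ppy at 36.4 ± 6.11 and 49.8 ± 25 (0.29, SE 0.37) and Iapp at 464 ± 71.3 and 341 ± 73 (-0.45, SE 0.22). The wide spread in knockouts came from replicate 1, where Ins1 was at 627, Sst at 151 and Ppy at 21 FPKM, against 235 and 233, 422 and 455, and 63.3 and 65.1 in replicates 2 and 3. Conversely, heterozygote replicate 1 had Ins1 at 315 and Sst at 375 FPKM, against 606 and 481, and 201 and 174, in the other heterozygotes. By limma 0 of 13306 genes were higher and 0 lower in knockouts, with 1117 genes under an unadjusted p of 0.05 where chance would give 665. This unadjusted count was 2628 without the library labelled knockout replicate 1, 717 without wild-type replicate 1, 603 without knockout replicate 3, 416 without wild-type replicate 2 and 399 without knockout replicate 2, 558 with sex as a covariate and 3730 with array weights, so the excess over chance depended on single libraries and on these settings. voom on the implied fragments also called 0, with 1166 under an unadjusted p of 0.05.

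**Figure D1:**
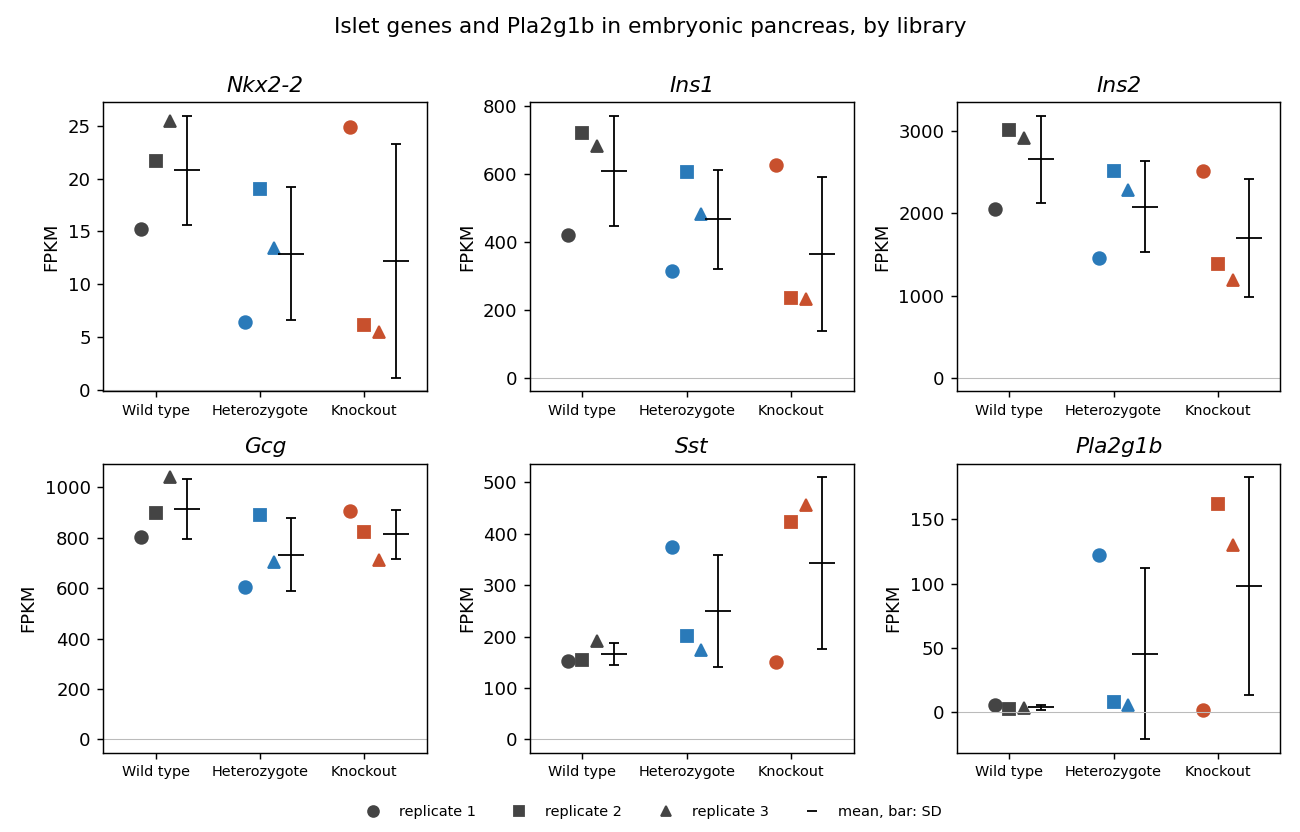
FPKM (vertical axes, linear) of the islet genes Nkx2-2, Ins1, Ins2, Gcg and Sst and of Pla2g1b in each library, grouped by labelled genotype, with symbols for replicate numbers and black bars for the mean and SD of 3 libraries. The library labelled knockout replicate 1 lies among the wild-type libraries at Nkx2-2, Ins1, Ins2 and Gcg, and just below them at Sst (151 against 152 to 191 FPKM) and Pla2g1b (1.81 against 2.35 to 5.54 FPKM).

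Transcription factor genes of the islet lineage did not pass, and as a list they were not called (16 of 22 members lower, limma camera adjusted p = 0.27). Pax6, a factor of endocrine cells, was at 11.3 ± 1.13 in wild type and 8.91 ± 2.02 in knockouts. Neurog3, which starts endocrine differentiation, was at 60.5 ± 11.2 and 51.4 ± 14.9, Neurod1 at 9.88 ± 0.434 and 7.96 ± 1.79, Mafa at 3.09 ± 0.84 and 2.29 ± 1.32, Rfx6 at 3.78 ± 0.478 and 3.32 ± 0.898 and Pax4 at 5.99 ± 1.03 and 5.18 ± 0.891. The means of Isl1, Insm1, Nkx6-1, Pdx1 and Sox9 lay closer together: 17.6 ± 0.588 and 16.5 ± 2.3 for Isl1, 11.7 ± 1.84 and 11.5 ± 3.05 for Insm1, 21.6 ± 3.09 and 21.7 ± 1.93 for Nkx6-1, 33.3 ± 3.06 and 35.8 ± 1.67 for Pdx1, and 24.7 ± 1.1 and 26 ± 0.311 for Sox9. For Isl1 and Insm1 the close means hide a split between knockout libraries. Isl1 was at 19.1 in replicate 1 and at 14.6 and 15.8 in replicates 2 and 3 (wild type 17 to 18.1). Insm1 was at 15.1, and at 9.86 and 9.71 (10.1 to 13.7). As a group, 19 of 23 endocrine progenitor genes were lower in knockouts, and the list was called by limma's camera (adjusted p = 0.014, and adjusted p = 0.65 with an estimated correlation). So were the beta cell list, with 12 of 16 members lower (adjusted p = 0.031), and the secretory granule list, with 20 of 24 lower (adjusted p = 0.014), each with adjusted p = 0.65 with an estimated correlation. Among their members with the smallest p were Cck, at 8.34 ± 1.28 and 5.68 ± 1.85, the granule protein gene Chga, at 109 ± 17.2 and 72.5 ± 27.5, and Pam, an enzyme of peptide amidation, at 42.4 ± 1.18 and 34.6 ± 7.13. The library labelled knockout replicate 1 was not lower at these genes. Cck was at 7.8 FPKM there (wild type 7.48 to 9.81, knockout replicates 2 and 3 at 4.39 and 4.86). Chga was at 104 (89.2 to 122, and 62.3 and 51.5) and Pam at 42.8 (41.1 to 43.1, and 30.8 and 30.2). Ero1lb of the beta cell list and Kcnj11 of the granule list had higher means in knockouts, 34.6 ± 1.98 against 40.9 ± 4.53 and 16.2 ± 1.72 against 19.8 ± 2.09. The lists of islet hormones (adjusted p = 0.30), alpha cells (0.063) and delta, epsilon and PP cells (0.50) were not called by camera, and the lists share members. With sex as a covariate the alpha cell list was called lower (limma camera adjusted p = 0.03, and adjusted p = 0.65 with an estimated correlation).

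Genes of exocrine and supporting tissue formed the other large groups in knockout against wild type. The acinar list was higher as a group, with 24 of 31 members higher (limma camera adjusted p = 7.8e-05, and adjusted p = 0.65 with an estimated correlation, as for each of the 6 lists that follow). Ptf1a, the master regulator of acinar cells, was at 75.7 ± 8.92 and 102 ± 16.3, Nr5a2 at 34.3 ± 4.93 and 40.6 ± 3.88, and Cpa1, a carboxypeptidase, at 8240 ± 353 and 9420 ± 2100. The library labelled knockout replicate 1 was not higher at these genes. Cpa1 was at 7460 FPKM there (wild type 7900 to 8600, knockout replicates 2 and 3 at 11600 and 9160). Ptf1a was at 85.2 (wild type 67.6 to 85.3, the other knockouts 118 and 103) and Nr5a2 at 36.8 (28.7 to 38.1, and 44.6 and 40.5). All 19 mesenchyme genes were lower (limma camera adjusted p = 6.8e-05), among them Tcf21 at 22.9 ± 3.33 and 14.9 ± 4.92 and Wt1 at 8.6 ± 1.1 and 5.99 ± 1.5. Both lay within the wild-type range in knockout replicate 1, Tcf21 at 20.2 (wild type 19.3 to 25.8) and Wt1 at 7.52 (7.46 to 9.67). All 16 endothelial genes were lower too (limma camera adjusted p = 7.8e-05), among them the adhesion molecule gene Esam at 28.3 ± 1.56 and 23.8 ± 2.63 and the receptor gene Tie1 at 22.2 ± 3.14 and 17.2 ± 2.62. Knockout replicate 1 was just below wild type at Esam (26.5 against 27.4 to 30.1) and Tie1 (19.4 against 19.5 to 25.6). Of the immune genes 15 of 17 were lower (limma camera adjusted p = 0.0011), among them the macrophage receptor gene Mrc1 at 7.99 ± 0.851 and 5.87 ± 0.965 and C1qb at 37.6 ± 4.86 and 26.6 ± 5.32. C1qa, the immune gene with the highest mean, was at 157 ± 12.5 and 142 ± 7.31. Knockout replicate 1 was below wild type at Mrc1 (6.81 against 7.01 to 8.53) and C1qb (32.1 against 34.3 to 43.2), but not at C1qa (147 against 144 to 169). Lists of the unfolded protein response (13 of 15 members higher, adjusted p = 0.00043), hypoxia (10 of 12 higher, 0.0069) and the cell cycle (18 of 27 higher, 0.014) were higher with small changes, with a median log2 change of 0.08, 0.07 and 0.04. Xbp1, a regulator of the unfolded protein response, was at 398 ± 39.5 and 455 ± 35.9, Ndrg1 of the hypoxia list at 89.1 ± 6.54 and 112 ± 15.7, and Rrm2 of the cell cycle list at 89.7 ± 6.19 and 96.6 ± 1.62. For these 7 lists fry, which does not compare a list with other genes, gave an adjusted p of 0.69 for the cell cycle and 0.5 for the other 6. With sex as a covariate the cell cycle list was no longer called (limma camera adjusted p = 0.39). 0 members of any list passed over all genes, and 0 passed adjusted over the list alone.

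**Figure D2:**
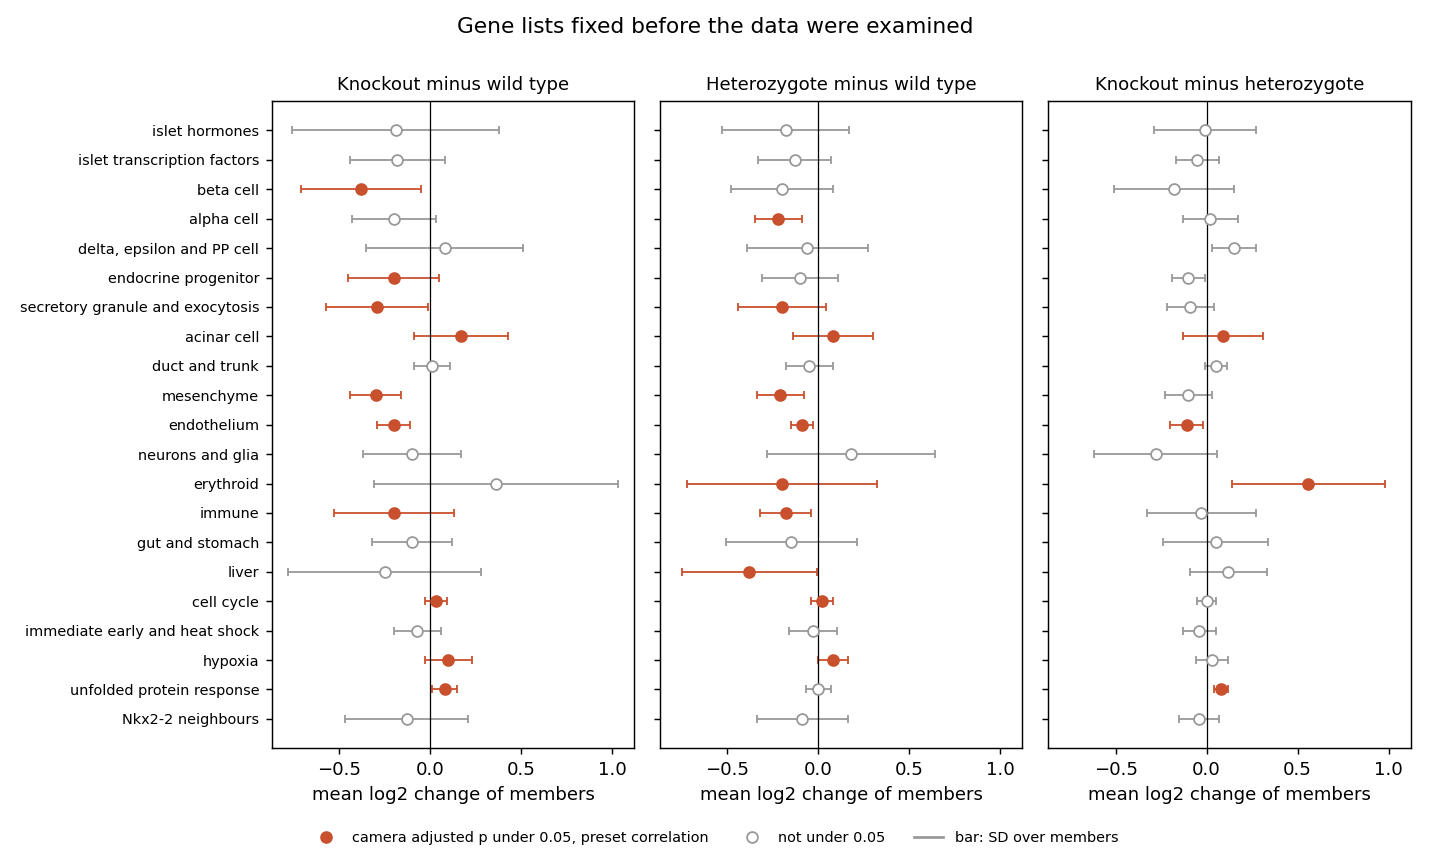
Mean log2 change of the members of each of 21 gene lists (horizontal axis, log2(FPKM + 1) scale) in the 3 comparisons, with bars for the SD over members and filled points where camera with the preset correlation gave an adjusted p under 0.05. Of the lists 10, 10 and 4 were called from left to right, and 0 in any comparison with an estimated correlation.

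Duct and trunk genes (10 of 17 higher, limma camera adjusted p = 0.30), neurons and glia (11 of 17 lower, 0.82), gut and stomach (4 of 6 lower, 0.96), liver (6 of 8 lower, 0.30), immediate early and heat shock genes (9 of 13 lower, 0.69) and erythroid genes (9 of 12 higher, 0.063) were not called between knockout and wild type. With sex as a covariate these lists were not called either, but the mean log2 change of the erythroid list moved from 0.36 to 0.84 (limma camera adjusted p = 0.05, at the threshold without passing it, and 0.65 with an estimated correlation), that of gut and stomach from -0.10 to -0.25 and that of liver from -0.25 to -0.06. The highest-level genes were Tff2 of the stomach at 33.5 ± 6.6 and 36.7 ± 5.49, Afp of the liver at 29.5 ± 9.7 and 26 ± 6, Ier2 at 45.7 ± 4.37 and 47 ± 1.76, and the haemoglobin gene Hba-a1 at 4410 ± 777 and 4640 ± 773. Hba-a1 has a near-identical copy, so its level is uncertain. Hba-a2 of the same list, named after its values were seen, was at 47.6, 661 and 0.000661 FPKM in wild-type replicates 1, 2 and 3. It was at 416, 361 and 0.000376 in heterozygotes and at 40, 252 and 341 in knockouts (log2 change 2.26, SE 2.67). The values near 0 are those of the only females outside the knockouts, so a sex covariate can move this gene strongly. Its share of the move in the erythroid mean was not tested.

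The single genes with the smallest p between knockout and wild type did not pass. Pim3, a kinase gene, was at 44.7 ± 1.62 and 55.7 ± 1.6, Rbks, encoding ribokinase, at 6.39 ± 0.207 and 9.65 ± 0.32, and the long intergenic noncoding RNA Gm11240 at 0.538 ± 0.152 and 1.43 ± 0.178. Lower were Lst1, a gene of leukocytes, at 12.3 ± 0.537 and 6.92 ± 0.69 (limma adjusted p = 0.25), Pros1, encoding protein S, at 13.5 ± 0.396 and 10 ± 0.67, and the microRNA gene Mir546 at 171 ± 120 and 3.38 ± 5.85. Mir546 is a short gene and rests on at most 3.78 implied fragments in a wild-type library and 0.0336 in a knockout library, and Gm11240 on 2.61 to 21 fragments in these libraries. The other 5 had a limma adjusted p of 0.58. In all 6 genes, picked for their p, every knockout library lay beyond every wild-type library, which chance gives for 10% of genes. Leaving out the library labelled knockout replicate 1 gave 1 gene, Eif3j, and leaving out wild-type replicate 1, wild-type replicate 2 or heterozygote replicate 1 gave 1 other gene each: Gm6644, Cd1d2 and Cyp2c70. These 4 names were chosen after their values were seen.

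Without the libraries labelled knockout replicate 1 and heterozygote replicate 1, a fit added after Nkx2-2 had been seen, limma called 3 genes higher and 1 lower in knockouts, with 2630 genes under an unadjusted p of 0.05. The genes were named after their values were seen. Pla2g1b, which encodes pancreatic phospholipase A2 (chromosome 5, 115916275 to 115924726), was at 162 and 130 FPKM in knockout replicates 2 and 3 and at 2.35 to 5.54 FPKM in wild type (log2 change 5.03, SE 0.27). Sst differed by 1.40 (SE 0.11) and Eif3j, a translation initiation factor gene (chromosome 2, 121854359 to 121879365), by 1.08 (SE 0.09), the latter from only 14.47 to 34.36 implied fragments in each library of this fit. Cyp2c70, a cytochrome P450 gene (chromosome 19, 40227851 to 40261776), was at 0.669 to 1.06 FPKM in all 3 knockout libraries and at 8.42 to 12.2 in wild type (-2.56, SE 0.16). Camera called 14 lists in this fit with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.46). Compared with the fit of all libraries, hypoxia was no longer called (limma camera adjusted p = 0.054). Newly called were islet transcription factors (lower, 0.0072), neurons and glia (lower, 0.02, median log2 change -0.50), alpha cells (lower, 0.046), delta, epsilon and PP cells (higher, 0.046) and erythroid genes (higher, 0.035). With an estimated correlation erythroid genes had an adjusted p of 0.46 and the other 4 of 0.54. The left-out libraries were picked for their Nkx2-2 level, so larger differences at Nkx2-2 and at genes that vary with it follow partly from that choice.

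Around Nkx2-2, 6 tested genes lay within 1 Mb. Foxa2, which encodes a forkhead factor of endoderm (chromosome 2, 147868614 to 147872705), was at 30.1 ± 1.61 in wild type and 34.5 ± 1.44 in knockouts (log2 change 0.19, SE 0.05). Plk1s1, a centrosome protein gene 0.27 Mb from Nkx2-2 (146681625 to 146795825), was at 17.5 ± 1.01 and 15.3 ± 0.458 (-0.19, SE 0.06). Both passed adjusted over the list alone (limma adjusted p = 0.039), and 0 of the 6 passed over all genes. Xrn2, Ralgapa2, Insm1 and Nkx2-2 did not pass, and camera did not call the window (p = 0.91, and p = 0.93 with an estimated correlation). Within 5 Mb 0 of 53 genes passed, and within 10 Mb 0 of 136, adjusted over the list alone. The count was 0 without any 1 of wild-type replicate 1, heterozygote replicate 1, heterozygote replicate 2, knockout replicate 2 or knockout replicate 3, and 1 without wild-type replicate 2 or 3, and without the library labelled knockout replicate 1 there were 4. The fixed list of Nkx2-2 neighbours was not called (limma camera adjusted p = 0.75).

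The comparison of heterozygotes with wild type asks whether loss of a single allele changes expression. Among genes lower in heterozygotes the smallest p belonged to Lst1, a gene of leukocytes, and to members of a family of predicted genes on chromosome 14, without passing the test. In this comparison 0 genes were higher and 0 lower by limma, with 522 under an unadjusted p of 0.05 where chance would give 665; voom called 0, with 505. The unadjusted count was 872 without wild-type replicate 3 and 277 without wild-type replicate 2. Lst1 came closest, at 12.3 ± 0.537 in wild type and 6.29 ± 0.742 in heterozygotes (log2 change -0.88, SE 0.09, limma adjusted p = 0.072), and all 3 heterozygote libraries lay below all wild-type ones. Next were genes of a family of similar predicted genes at the start of chromosome 14: Gm5796 (4126977 to 4144402) at 3.03 ± 0.889 and 0.566 ± 0.169, and Gm3696 (7915539 to 7937971) at 5.96 ± 1.68 and 0.804 ± 0.288. Reads can be shared between such copies, so the level of each member is uncertain. In knockout replicates 2 and 3 Gm3696 was at 3.71 and 4.41 FPKM and Gm5796 at 1.98 and 2.1 FPKM, all above every heterozygote library. In the library labelled knockout replicate 1 they were at 0.976 and 0.859 FPKM. The lower level of these genes thus did not follow the labelled number of lost alleles. Higher without passing were Alg3, a glycosylation gene, at 22.6 ± 1.15 and 27.3 ± 1.08, Kctd1 at 4.25 ± 0.31 and 5.81 ± 0.506, and Tmem126a at 45.8 ± 1.51 and 53.9 ± 0.987. With only these genotypes in the fit, Lst1, Gm3696 and 4 further members of the family (Gm10406, Gm2897, Gm3383 and Gm8348, named after their values were seen) passed, all lower. Without the library labelled knockout replicate 1, 7 genes passed, without heterozygote replicate 2, 2 passed (Lst1 and Rps19, the latter named after its values were seen), and without wild-type replicate 1, Gm6644, likewise named afterwards, passed as higher. Without the libraries labelled knockout replicate 1 and heterozygote replicate 1, there were 5 (also named afterwards: Gm10406, Gm2897, Gm3383, Gm3696 and Gm8348), with 644 genes under an unadjusted p of 0.05.

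Among the gene lists in heterozygotes against wild type, camera with the preset correlation called 10. Lower were alpha cell genes (11 of 11 members, limma camera adjusted p = 0.0026), mesenchyme (17 of 19, 0.0026), erythroid (9 of 12, 0.013), immune (15 of 17, 0.013), liver (6 of 8, 0.015), endothelium (14 of 16, 0.035) and secretory granule genes (18 of 24, 0.039). Higher were acinar genes (20 of 31, 0.013), hypoxia (11 of 12, 0.028) and the cell cycle (18 of 27, 0.039). None held with an estimated correlation (smallest adjusted p = 0.78). Examples were the alpha cell factor Pou3f4 at 1.76 ± 0.101 in wild type and 1.05 ± 0.127 in heterozygotes, the mesenchymal factor Nkx3-2 at 1.62 ± 0.288 and 0.993 ± 0.249, the haem synthesis gene Alas2 at 35.9 ± 9.73 and 22.3 ± 6.05, Csf1r at 14.7 ± 2.24 and 11.1 ± 2.02, and Fgb, a fibrinogen chain of the liver, at 1.68 ± 0.127 and 0.929 ± 0.209. Fgb was the 1 member of any list that passed adjusted over the list alone. The lists of islet hormones (0.17), islet transcription factors (0.36), beta cells (0.098), delta, epsilon and PP cells (0.39), endocrine progenitors (0.37), duct and trunk (0.65), neurons and glia (0.39), gut and stomach (0.60), immediate early and heat shock (0.93), the unfolded protein response (0.40) and Nkx2-2 neighbours (0.65) were not called; for neurons and glia the test pointed up and the mean log2 change was 0.18, while the median was -0.03. Ptf1a was at 75.7 ± 8.92 and 92.5 ± 8.79. Leaving out wild-type replicate 2 left 2 lists called, and leaving out the library labelled heterozygote replicate 1 left 5. Without the libraries labelled knockout replicate 1 and heterozygote replicate 1, 7 lists were called, and endothelium (limma camera adjusted p = 0.14), hypoxia (0.36, with a median log2 change of 0) and the cell cycle (0.062) were not. With an estimated correlation camera called 0 lists in that fit (smallest adjusted p = 0.87).

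Between knockouts and heterozygotes, erythroid genes differed most as a group. Erythroid genes were higher as a list (11 of 12 members, limma camera adjusted p = 1.9e-08, and adjusted p = 0.08 with an estimated correlation), among them the embryonic globin gene Hba-x at 8.5 ± 3.49 and 14.6 ± 1.27 and Alas2 at 22.3 ± 6.05 and 37.1 ± 9.02. The unfolded protein response (15 of 15 higher, 0.00027) and acinar genes (22 of 31 higher, 0.044) were also called, and endothelium was lower (15 of 16, 0.0057). With an estimated correlation each of these 3 had an adjusted p of 0.86. Herpud1 was at 126 ± 2.76 and 142 ± 18.6, Reg1 at 292 ± 28.5 and 399 ± 139, and Tie1 at 20.1 ± 1.54 and 17.2 ± 2.62. Of single genes 0 were higher and 0 lower by limma, with 296 under an unadjusted p of 0.05 where chance would give 665; voom called 0, with 275. The unadjusted count was 1189 without the library labelled knockout replicate 1, 557 without heterozygote replicate 2, 185 without knockout replicate 2 and 1706 with array weights. The genes with the smallest p had a limma adjusted p of 1. They were Steap1 at 2.33 ± 0.11 in heterozygotes and 3.78 ± 0.326 in knockouts, Eapp at 26.5 ± 1.07 and 31.3 ± 0.539, Gm11240 at 0.649 ± 0.0596 and 1.43 ± 0.178, and, lower in knockouts, Gm7367 at 52.3 ± 2.28 and 42.3 ± 1.91, Mir546 at 91.6 ± 70.8 and 3.38 ± 5.85 (from at most 1.77 implied fragments in a heterozygote library), and Trim12a at 4.33 ± 1.63 and 1.58 ± 0.261. Of the other 17 lists none was called (smallest camera adjusted p = 0.052, for endocrine progenitors). Without heterozygote replicate 2, 11 lists and 1 gene (Rps19) were called, without heterozygote replicate 1, 1 gene (Cyp2c70), both named after their values were seen, and without the library labelled knockout replicate 1, 13 lists and 4 genes of the chromosome 14 family (Gm10406, Gm2897, Gm3383 and Gm8348). Without knockout replicate 2, 2 lists were called. Without the libraries labelled knockout replicate 1 and heterozygote replicate 1, camera called 12 lists with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.45). In that fit Gm3383, Gm8348, Pla2g1b and Sst were higher and Cyp2c70 lower, all named after their values were seen, with 862 genes under an unadjusted p of 0.05.

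The comparisons of knockouts and of heterozygotes with wild type used the same 3 wild-type libraries. Their log2 changes had a Pearson correlation of 0.635 across genes and a covariance of 0.0198. In 100 simulations all 3 groups, wild type included, were drawn with no effect and with independent genes. Against the simulated shared wild type the correlation was 0.506 ± 0.06 and the covariance 0.0153 ± 0.0027 (SD over simulations). Of all genes 75.9% had log2 changes of the same sign, against 66.8% ± 0.37 in the simulation. The simulated values already include a shared wild type, but genes of the data are not independent, so the simulated SDs are too narrow for them. With 3 wild-type libraries the controls could not be split, so the excess cannot be told from variation of the shared controls. No gene passed in both comparisons, where chance would give 0. Lst1 was at a similar level in both mutant groups, 6.29 ± 0.742 and 6.92 ± 0.69.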

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

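All tests in this part were chosen only after the results were seen. High values outside the tested genes came from small RNA genes that were at 0 or near 0 FPKM in every wild-type library and at 100 FPKM or more in another library. Mir682 was at 639705 FPKM in heterozygote replicate 3, Mir1966 at 377 in heterozygote replicate 2, Snora31 at 325 in knockout replicate 3, Mir719 at 260 in heterozygote replicate 1 and Snora44 at 112 in heterozygote replicate 3. Their loci are 96 to 117 bp long, and 4 of the 5 were above 1 FPKM in 1 library only. At Mir546, also a short gene, 272 FPKM in wild-type replicate 2 rested on 3.78 implied fragments. A high FPKM at such loci therefore need not mean many fragments. No explanation was tested for these values.

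Scored over the genes that best set knockout replicates 2 and 3 apart, the library labelled knockout replicate 1 lay near the wild types and heterozygote replicate 1 beyond the other heterozygotes: on a scale from 0 (wild-type mean) to 1 (mean of knockout replicates 2 and 3) over 50 genes ranked without both libraries, they had -0.05 and 0.48 by the per-gene median, and -0.01 and 0.79 by a projection, both tried after the data were seen. Other genes placed knockout replicate 1 elsewhere: of 9 genes called in any comparison without both libraries, 6 were more than 1 log2 unit outside their wild-type range in knockout replicate 1, 5 of them from the chromosome 14 family. Cyp2c70 was at 0.895 FPKM there (wild type 8.42 to 12.2, other knockouts 0.669 and 1.06, heterozygote replicate 1 at 0.159 and the other heterozygotes at 9.41 and 11.1), the chromosome 14 gene Gm3383 at 1.86 (wild type 11.4 to 15.7, heterozygotes 2.32 to 2.4, other knockouts 10.6 and 12.8), and Lst1 at 7.29 (wild type 11.8 to 12.8), while Pla2g1b in heterozygote replicate 1 was at 122 (other heterozygotes 8.29 and 5.66, knockout replicates 2 and 3 at 162 and 130). A wild-type library under the knockout label may account for the score, 0.65 SD of the wild-type scores from their mean, but not for these genes unless they vary between wild-type embryos of the mixed background, which was not tested. An exchange of the labels was not decided. Heterozygote replicates 2 and 3 scored 0.36 and 0.28 by the median, and 0.28 and 0.20 by the projection. Knockout replicate 1 lay more than 2 SD of the wild-type scores below them by the median (SD 0.08), but not by the projection (SD 0.12). For an exchange, Gm3383 put knockout replicate 1 with the heterozygotes, and Cyp2c70 and Pla2g1b put heterozygote replicate 1 with knockout replicates 2 and 3. Against it, Cyp2c70 put knockout replicate 1 with the other knockouts, and Gm3383 put heterozygote replicate 1 with the other heterozygotes. A knockout library under the heterozygote label (knockout replicates 2 and 3 are at 1 by construction) stays open, as the same genes divide on it. So does a biological difference between embryos.

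Other splits of the 6 libraries of each comparison were also counted. There are 10 such splits, too few for a share under 0.05, and with a real count of 0 all 10 reach it by construction, so the count of splits says nothing about chance. For knockout against wild type the real count was 0 and the highest other was 1, for heterozygote against wild type 0 and 2, and for knockout against heterozygote 0 and 409. The split with 409 genes set heterozygote replicates 1 and 3 and knockout replicate 1 against heterozygote replicate 2 and knockout replicates 2 and 3. It was picked for its count, and what sets these libraries apart was not tested. Along the axis of largest variation between the 9 libraries (first principal component, 31.1% of the variance), the first side lay at -12.1, -2.79 and -12.4. The other side lay at 11.3, 23.8 and 14.3, and the wild-type libraries at -7.02, -15.8 and 0.863. Acinar and haemoglobin genes, those failed for excess data left out, made up 3.993, 4.454 and 3.543% of the implied fragments on the first side. On the other side they made up 4.909, 6.14 and 4.66%.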

How the results depend on the processing

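Chosen only after the data were seen were the fits without heterozygote replicate 1 and knockout replicate 1, voom on the implied fragments, and the fit without small RNA genes. For 117 results for genes under the naming rule, those of the 27 other settings that refitted single genes gave 2553 values. Of these values 2499 kept their direction and side of the threshold, 38 passed the threshold in the same direction, and 16 reversed. In the main fit 0 genes passed in any comparison, so keeping the side meant only that a gene still did not pass. The 2499 values therefore do not measure how stable a call is. The cause of the changes between settings was not tested, except that camera with an estimated correlation and fry differ from the preset correlation by construction. Depth is only implied, and genes near 1 FPKM, short small RNA genes at any FPKM and some others such as Eif3j rest on few fragments.

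The replicate numbers were also fitted as a block. With the replicate block 1 gene was lower in heterozygotes against wild type (Lst1), and the count near Nkx2-2 was 0. Residuals of libraries with the same number correlated between -0.19 and 0.29, not all above 0.1, and wild-type replicate 2 correlated best with heterozygote replicate 1 (0.28), so the numbers were not taken to pair the libraries; the labels do not say whether they do.

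With only the compared genotypes in the fit 1 gene was lower in knockouts against wild type (Cyp2c70), 6 were lower in heterozygotes, and 0 passed near Nkx2-2. With sex as a covariate Nkx6-1 was at -0.08 and Ier2 at -0.01 for knockout against wild type, 2 lists were called for knockout against heterozygote, and 1 gene passed near Nkx2-2. Quantile normalization gave Insm1 0.02 and Hba-a1 -0.05, with 1 gene near Nkx2-2. With array weights, where knockout replicate 3 had a weight of 5.73 and knockout replicate 1 of 0.446, 2 genes were higher (Pim3 and Rbks) and 3 lower (Ccl21a, named after its values were seen, Lst1 and Pros1) in knockouts against wild type, Nkx6-1 was at -0.03, 10 lists were called for knockout against heterozygote, and 4 genes passed near Nkx2-2. Rescaling without acinar and haemoglobin genes, and voom, each left 1 gene near Nkx2-2. Windows of 5 and 10 Mb gave 0. Camera with an estimated correlation and fry called 0 lists in each of the 3 comparisons. Without heterozygote replicate 1 and knockout replicate 1, 3 genes were higher and 1 lower for knockout against wild type, 5 lower for heterozygote against wild type, and 4 higher and 1 lower for knockout against heterozygote. For the last, 12 lists were called with the preset correlation and 0 with an estimated one. Nkx6-1 was at -0.05 for knockout against wild type.

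Leaving out each library in turn gave, for knockout against wild type, 0 to 1 genes higher and 0 to 1 lower; for heterozygote against wild type, 0 to 1 higher, 0 to 7 lower and 2 to 15 lists; and for knockout against heterozygote, 0 to 4 higher, 0 to 1 lower and 2 to 13 lists. Near Nkx2-2 it gave 0 to 4 genes. In knockout against wild type Insm1 ranged from -0.22 to 0.08, Nkx6-1 from -0.07 to 0.12, Hba-a1 from -0.03 to 0.21, Afp from -0.32 to 0.1 and Ier2 from -0.01 to 0.12. Pla2g1b in knockout against heterozygote ranged from -0.04 without knockout replicate 2 to 2.89 without knockout replicate 1. The counts of 7 and 4 genes and 13 lists came without knockout replicate 1, that of 15 lists without heterozygote replicate 2, and those of 2 lists without wild-type replicate 2 and knockout replicate 2.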

Other observations

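All tests in this part were chosen only after the results were seen, except the test of sex. In knockout against wild type the acinar list was higher, and the mesenchyme, endothelium and immune lists were lower, each with a limma camera adjusted p of 0.65 with an estimated correlation. A larger share of acinar cells would lower the markers of every other cell type alike. The 17 duct and trunk genes had a mean log2 change of 0.01, against -0.24 for the 52 mesenchyme, endothelium and immune genes. These were 6.4 standard errors over genes apart but only 1.2 by the spread between libraries. The duct and trunk list also holds genes of epithelium in general, such as Epcam and Cdh1, which need not fall with a larger acinar share. A larger acinar share therefore stays open. A smaller share of non-epithelial tissue may also account for the lower lists, and the neurons and glia list, with a mean of -0.10, lay 1.9 standard errors over genes and 0.36 by the spread between libraries from them; without the libraries labelled knockout replicate 1 and heterozygote replicate 1 it was called lower (median -0.50, limma camera adjusted p = 0.02, and adjusted p = 0.54 with an estimated correlation), so this stays open as well. With sex as a covariate the mesenchyme list had a camera adjusted p of 0.0047, under the threshold set for that test, but 0.65 with an estimated correlation; as its members were correlated at 0.53 and not at the preset 0.01, that threshold does not exclude sex, although the mean log2 change moved only from -0.30 to -0.26. A change in the mesenchyme itself was not tested.

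Around Nkx2-2, flanking sequence of the targeted strain, left beside the locus, might change the expression of linked genes. Of 135 genes within 10 Mb, Nkx2-2 left out, 16 had an unadjusted p under 0.05 (11.9%, against 8.36% elsewhere; one-sided Fisher exact p = 0.1). The Fisher test takes genes as independent, but the same libraries gave every p, so it does not measure the spread between libraries. The hypothesis stays open, since the share was higher without passing.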
